A study of Homo sapiens with 6 samples.

How the data were processed

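RNA was measured in 6 libraries of SW480 tumour cells recovered from mouse livers, 3 with a control guide (sgCtrl) and 3 with a guide against ITPR3 (sgITPR3). Per the labels, the knockout had been checked on Western blots, livers were digested with collagenase, and mouse cells were depleted before RNA was prepared with a Norgen kit. Libraries were made from polyadenylated RNA with the Lexogen 3' FWD kit.

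The values analysed are the gene counts as deposited. Per the submitters' processing notes, the authors aligned reads to GRCh38 with STAR 2.6.0a, made the counts with featureCounts 1.6.3 and compared the groups with DESeq2. The annotation release, the strand setting and the treatment of mouse reads and of reads with several alignments are not given in the sources used here. All 58884 gene identifiers were kept as deposited. Of these, 30264 had a count in any library, 58641 received a symbol, and positions came from GENCODE release 29.

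Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 15804 genes holding 99.8% to 99.9% of the counts of each library. Library sizes were scaled by TMM (factors 0.961 to 1.03), and CPM are counts over the scaled library size. The quasi-likelihood F test of edgeR compared sgITPR3 with sgCtrl without further covariates. Adjustment was by Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 passed. The SE of a log2 fold change is its absolute value over the square root of F. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 27 lists with at least 5 tested members. Of 32 lists, 5 had fewer (metallothioneins and the markers of macrophages, neutrophils, endothelium and erythroid cells). An adjusted p over the list alone was also computed for its members.

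Totals were from 19140055 to 23943797 counts per library. A single count is 0.0404 to 0.0537 CPM, so a floor of 3 counts is 0.121 to 0.161 CPM. The most abundant gene held 8.26% to 8.87% of counts and mitochondrially encoded genes 19.6% to 21.3%. The biological coefficient of variation was 9.53%. Libraries of a group correlated at 0.982 to 0.991 on the log2 scale, and their chi-square per degree of freedom was 6.11 to 11.7, so none repeats the counts of another.

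Groups follow the sample labels. Gene lists, the test, the main alternatives and the rule for naming genes were fixed before the data were examined. The rule names ITPR1, ITPR2, ITPR3, RELB and NFKB2, and the 10 largest rises and falls among passing genes with a mean of at least 5 CPM and no overlap between groups. It also names up to 4 members with the smallest p from each list that was called or held a passing member, and at most 2 from any other list. ALB, the chromosome 12 neighbours and list members that went against their list, or are given as extra examples, were named after the values were seen. Some list members that the rule names are not reported here. XIST and Y-linked genes were left out of the naming and the plots.

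Alternatives were RLE scaling, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, a 2-fold threshold, camera with an estimated correlation, and fry. Added after the data were seen were the ALB level as a covariate, a correction for GC content over 500 bases of the transcript end, and a fit without chromosome 17.

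The procedure was tested on simulated data with 200 changed genes among 15804. It recovered 57.0% of changes of 1.5-fold, 72.5% of changes of 2-fold and 95.5% of changes of 4-fold. Of the calls, 7.32%, 9.38% and 9.48% were false, which is above the nominal rate. In the data far more genes were called (3717), and both kinds of share depend on how many genes change, so they need not hold there. With no change planted, 0 genes and 0 lists were called. Genes were simulated independently of each other, so this cannot show how list calls behave when members are correlated. A change of -0.3 planted in the cholesterol list led to a call of that list alone, and a chromosome 17 shift of 0.25 was recovered as 0.253.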

Results

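Gene expression was measured in liver metastases grown from SW480, an established human colorectal cancer cell line. The cells carried either a control guide RNA (sgCtrl) or a guide RNA against ITPR3 (sgITPR3), and reached the liver through the portal blood of NSG mice, an immunodeficient strain that accepts human tumours. Tumour cells were recovered from the dissociated livers and their polyadenylated RNA was sequenced as tags from the 3' ends of transcripts. There were 3 libraries of each group. Gene counts summed to 19361145, 20049117 and 19255242 in sgCtrl replicates 1 to 3, and to 22893501, 23943797 and 19140055 in sgITPR3 replicates 1 to 3. The labels do not say that each library came from its own animal, so p-values measure only the spread between these samples. Levels are counts scaled to library size (CPM) as mean ± SD over n = 3 libraries per group, and coordinates are those of GRCh38.

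The targeted gene was examined first. ITPR3 (ENSG00000096433, chromosome 6, 33620365 to 33696574) encodes the type 3 inositol trisphosphate receptor, a channel that releases calcium from the endoplasmic reticulum. Its level was 107.5, 93.9 and 94.2 CPM in the sgCtrl libraries and 39.4, 41.0 and 46.2 CPM in the sgITPR3 libraries, which is 2.34-fold lower in sgITPR3 (log2 fold change -1.22, SE 0.083, edgeR adjusted p = 1.28e-07). Each sgITPR3 library lay below every sgCtrl library. A 3' tag can lie outside the edited part of a gene, and the guide position is not given in the sources used here, so the remaining transcript says nothing about how much protein remained. Of the related receptors, ITPR2 fell from 115 ± 5.31 to 74.5 ± 3.20 CPM (log2 fold change -0.62, SE 0.069, edgeR adjusted p = 1.63e-05). ITPR1 was measured at 2.62 ± 1.52 and 4.23 ± 0.656 CPM and did not pass the test (log2 fold change 0.68, edgeR adjusted p = 0.138). Without sgCtrl replicate 2 its log2 fold change was 1.25 (edgeR adjusted p = 0.00223), and with the level of ALB, a liver transcript, as a covariate it was -0.000625.

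**Figure D1:**
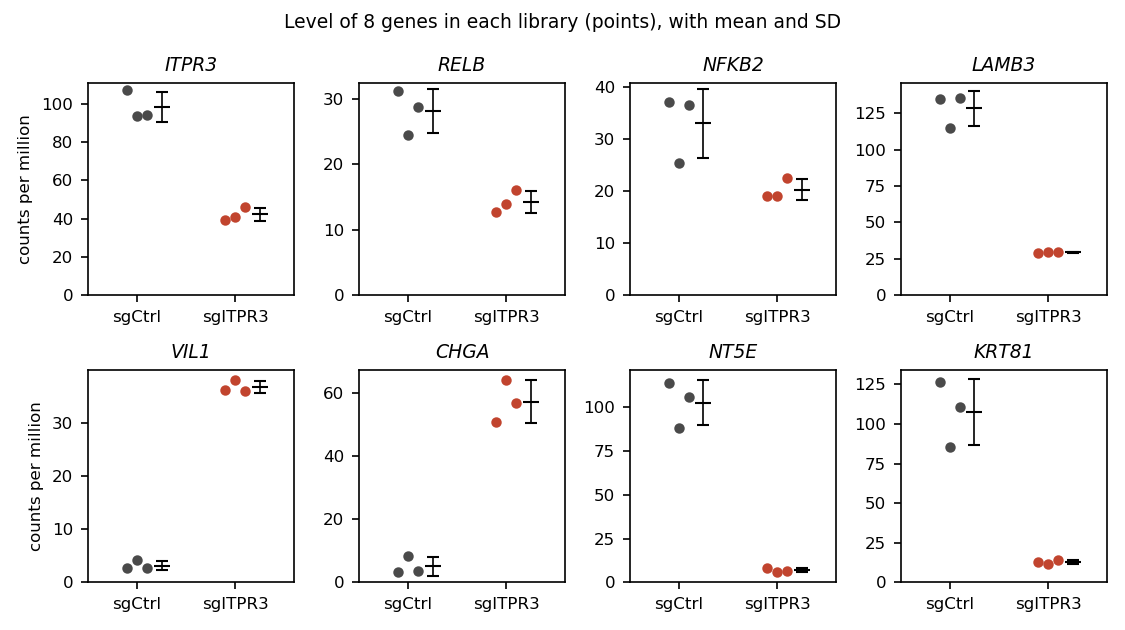
Level of 8 genes in each library, in CPM on linear axes from 0, for sgCtrl (grey points) and sgITPR3 (red points), with the mean and SD of n = 3 beside the points. ITPR3, RELB, NFKB2, LAMB3, NT5E and KRT81 lie lower in all 3 sgITPR3 libraries than in any sgCtrl library, and VIL1 and CHGA lie higher.

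The comparison of sgITPR3 with sgCtrl metastases asked which genes and pathways differ when ITPR3 is targeted. The 10 largest rises, by the rule for naming genes, included VIL1, CHGA, SCG3 and PCLO, and the 10 largest falls included NT5E, PLAT and the keratin genes KRT6A, KRT75 and KRT81. VIL1 (chromosome 2, 218419092 to 218453295), which encodes the microvillus protein villin, rose 11.5-fold from 3.18 ± 0.821 to 36.7 ± 1.19 CPM (log2 fold change 3.52, SE 0.141, edgeR adjusted p = 1.30e-09). CHGA, encoding the secretory granule protein chromogranin A, rose from 5.07 ± 2.93 to 57.1 ± 6.71 CPM. The granule protein gene SCG3 rose from 5.23 ± 1.74 to 54.6 ± 6.903 CPM. PCLO, encoding a scaffold of the presynaptic active zone, rose from 4.01 ± 1.04 to 38.3 ± 0.769 CPM, and SRRM3, a splicing regulator of neural exons, from 1.13 ± 0.579 to 12.4 ± 1.97 CPM. The other genes among the 10 largest rises were BMAL2-AS1, MYO3B, CLRN3, MUCL1 and TTN, with log2 fold changes from 2.99 for MUCL1 to 3.94 for BMAL2-AS1. TTN varied most within a group, at 7.74, 21.6 and 0.747 CPM in the sgCtrl libraries against 84.8 ± 19 CPM in sgITPR3.

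The largest fall was that of NT5E (chromosome 6, 85449584 to 85495791), which encodes the ecto-enzyme CD73 that makes adenosine from AMP. Its level went from 102 ± 12.9 to 6.904 ± 1.06 CPM, 14.8-fold lower (log2 fold change -3.89, SE 0.121, edgeR adjusted p = 1.31e-10). PLAT, the tissue plasminogen activator, fell from 17.5 ± 3.79 to 1.504 ± 0.219 CPM. The cytokine genes IL24 and IL32 fell from 11.8 ± 2.17 to 1.19 ± 0.434 CPM and from 9.53 ± 1.32 to 1.25 ± 0.112 CPM. Of the keratins, KRT75 fell from 88.5 ± 12.3 to 11.2 ± 1.93 CPM, KRT81 from 107 ± 20.5 to 12.8 ± 1.27 CPM and KRT6A from 14.2 ± 0.834 to 1.52 ± 0.398 CPM. KRT81 and KRT6A have close paralogs, so their counts are uncertain to the extent that reads were shared. SLIT3, encoding a secreted guidance protein, fell from 62.0 ± 1.54 to 6.92 ± 2.42 CPM. PAEP, encoding a secreted lipocalin, fell from 43.1 ± 9.65 to 4.61 ± 2.42 CPM, and TNC, encoding the matrix protein tenascin C, from 33.7 ± 6.74 to 5.22 ± 0.809 CPM.

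**Figure D2:**
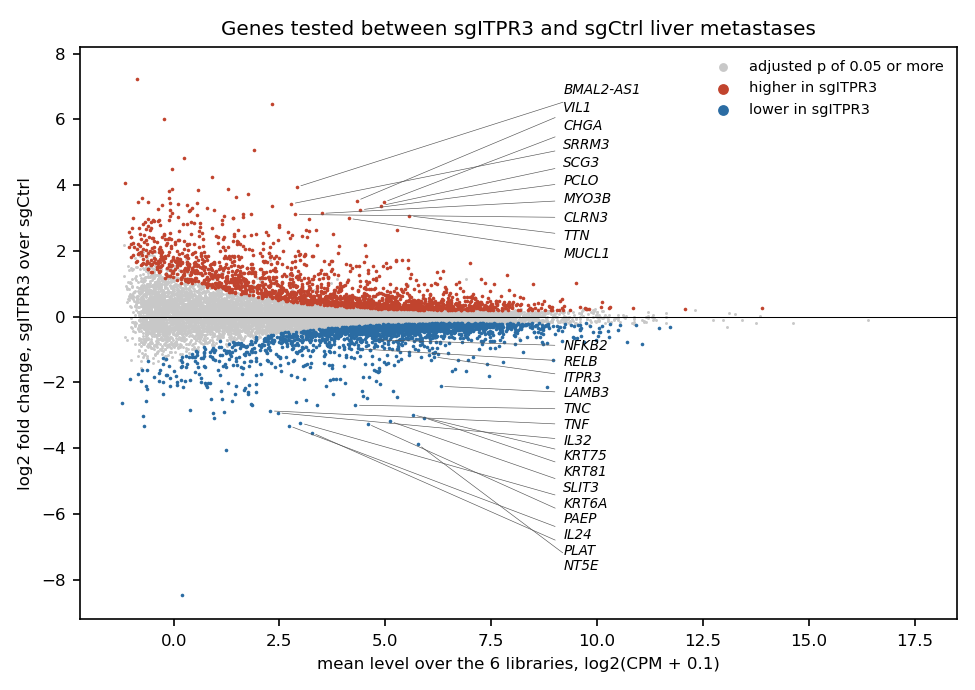
Log2 fold change of each tested gene (sgITPR3 over sgCtrl) against its mean level over the 6 libraries, log2(CPM + 0.1), with genes higher in sgITPR3 at an adjusted p under 0.05 in red, lower in blue and the rest in grey. The 10 largest rises and falls are labelled, from BMAL2-AS1 at 3.94 to NT5E at -3.89, together with ITPR3, RELB, NFKB2, LAMB3 and TNF. Genes of lower abundance can have larger values.

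BMAL2-AS1 (chromosome 12, 27389789 to 27446625, minus strand) is an antisense transcript that overlaps the end of BMAL2. It rose 15.3-fold, from 0.900 ± 0.230 to 13.9 ± 1.31 CPM. Since strand handling of the counts is not given in the sources used here, its reads cannot be told from those of overlapping genes. Its neighbours were examined after these values were seen. SMCO2 rose 6.21-fold, from 10.7 ± 0.457 to 66.2 ± 2.39 CPM, and PPFIBP1, which encodes a liprin, rose 2.04-fold, from 476 ± 58.7 to 971 ± 26.01 CPM. The flanking genes BMAL2 and MRPS35 had log2 fold changes of -0.16 (edgeR adjusted p = 0.309) and -0.14 (edgeR adjusted p = 0.206).

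**Figure D3:**
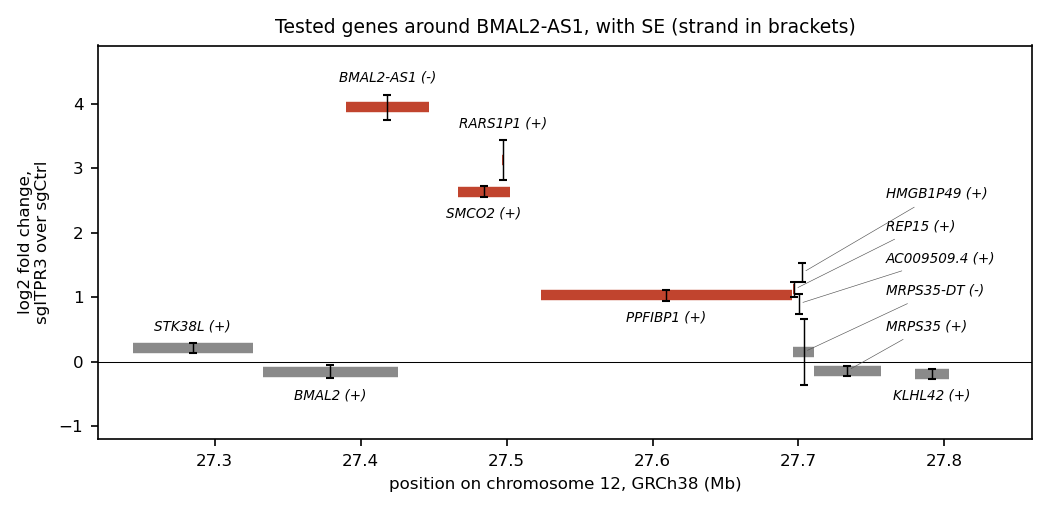
Log2 fold change (sgITPR3 over sgCtrl, bars as wide as the gene, whiskers of 1 SE) of 12 neighbouring tested genes by position on chromosome 12 in Mb. The 7 genes higher at an adjusted p under 0.05 are in red and lie between 27389789 and 27702906, and the genes on both flanks, in grey, lie near 0.

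Non-canonical NF-kB genes fell as a list (camera adjusted p = 0.00192; adjusted p = 0.142 with an estimated correlation). RELB, the transcription factor subunit that acts at the end of this pathway (chromosome 19, 45001430 to 45038198), went from 28.1 ± 3.36 to 14.2 ± 1.65 CPM, 1.98-fold lower (log2 fold change -0.98, SE 0.116, edgeR adjusted p = 2.93e-05). Its partner gene NFKB2 (chromosome 10, 102394110 to 102402529) fell from 33.0 ± 6.68 to 20.2 ± 2.02 CPM (log2 fold change -0.71, SE 0.133, edgeR adjusted p = 0.00151). The receptor gene TNFRSF12A fell from 73.5 ± 14.3 to 43.6 ± 5.14 CPM and BIRC3, which encodes a ubiquitin ligase of the pathway, from 20.4 ± 2.22 to 11.2 ± 2.19 CPM. Of 13 tested members of the non-canonical list, 8 fell, 0 rose and 5 did not pass, and 9 fell and 1 rose when adjusted over the list alone. With ALB as a covariate the log2 fold change of NFKB2 was -0.36 and its call ended (edgeR adjusted p = 0.0633), and that of TNFRSF12A went from -0.76 to -0.45 (edgeR adjusted p = 0.0120). That covariate was chosen after the ALB counts were seen.

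NF-kB target genes also fell as a list (camera adjusted p = 9.03e-15; adjusted p = 0.129 with an estimated correlation). Here and below, members that moved against the direction of their list are named after their values were seen. LAMB3, encoding a chain of laminin 332, went from 128 ± 11.9 to 29.5 ± 0.455 CPM, 4.34-fold lower (log2 fold change -2.12, SE 0.081, edgeR adjusted p = 9.10e-10). PLAUR, the urokinase receptor gene, fell from 90.5 ± 4.97 to 39.9 ± 1.9 CPM and BCL3, encoding a nuclear regulator of NF-kB dimers, from 26.8 ± 1.27 to 11.2 ± 0.588 CPM. TNF fell 7.30-fold from a low level of 8.41 ± 1.01 to 1.12 ± 0.440 CPM. Of 18 tested members, 12 fell, 2 rose (NFKBIZ and CCL20, the latter with a log2 fold change of 2.41) and 4 did not pass, with 14 lower and 2 higher when adjusted over the list alone.

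Most of the intestinal epithelial genes that could be tested rose in sgITPR3. Of 20 listed members, only 7 passed the low-count filter, which a gene can pass through a high level in sgITPR3 alone. Of these 7, 6 rose and 1 fell, with the same numbers when adjusted over the list alone (camera adjusted p = 9.03e-15; adjusted p = 0.129 with an estimated correlation). Without the filter, 18 members were tested and the list was called higher (camera adjusted p = 6.71e-15). Besides VIL1, the trefoil peptide gene TFF3 rose from 4, 7 and 1 counts in the sgCtrl libraries to 123, 237 and 124 counts in the sgITPR3 libraries. HNF4A, encoding a transcription factor of liver and gut epithelium, rose 2.97-fold from 4.31 ± 0.405 to 12.8 ± 0.400 CPM. The mucin gene MUC13 rose 5.05-fold from 1.77 ± 0.669 to 9.02 ± 0.909 CPM. The member that fell was EPCAM, with a log2 fold change of -0.32. CDX2 rose least, by 0.34 on the log2 scale (also named after its value was seen). The hepatocyte transcript ALB overlapped between groups. It was at 33.8, 169.7 and 21.6 CPM in the sgCtrl libraries and 231.6, 152.6 and 111.5 CPM in the sgITPR3 libraries. In sgCtrl replicate 2, whose ALB level lay within the sgITPR3 range, the list member FABP1 was 5.22 times its mean in the other sgCtrl libraries, TFF3 was 2.59 times, MUC13 1.82 times, VIL1 1.52 times, HNF4A 1.17 times and CDX2 0.867 times.

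Mesenchymal and invasion genes went both ways, with more falls than rises. Of 20 tested members, 10 fell, 4 rose and 6 did not pass, with 10 lower and 6 higher when adjusted over the list alone (camera adjusted p = 7.86e-04 for a fall; adjusted p = 0.129 with an estimated correlation). The urokinase gene PLAU fell 6.45-fold from 18.0 ± 2.35 to 2.81 ± 0.430 CPM. TGFBI, encoding a matrix protein, fell from 713 ± 12.8 to 285 ± 36.0 CPM. The members that rose were CDH2, CCN2, FN1 and TPM2, of which CDH2, encoding N-cadherin, had the largest log2 fold change (1.54). Wnt and beta-catenin targets were not called as a list (7 of 20 rose, 3 fell and 10 did not pass, and 8 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.109). The list was called higher without sgITPR3 replicate 3 (camera adjusted p = 0.0322) and without a low-count filter (camera adjusted p = 0.0226). Among them BMP4 rose 2.81-fold from 24.1 ± 2.89 to 67.8 ± 2.32 CPM, EPHB3 rose from 2.74 ± 0.501 to 7.28 ± 0.599 CPM and LEF1 from 51.2 ± 0.490 to 81.0 ± 7.21 CPM. CD44, encoding a hyaluronan receptor, fell from 241 ± 4.38 to 171 ± 7.68 CPM.

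Immediate early genes, which respond within minutes to growth factors and stress, were lower in sgITPR3. Of 20 tested members, 14 fell, 1 rose (BTG2) and 5 did not pass, with 14 lower and 2 higher when adjusted over the list alone (camera adjusted p = 9.64e-06; adjusted p = 0.251 with an estimated correlation). KLF6 fell 2.13-fold from 413 ± 50.4 to 194 ± 23.0 CPM, KLF2 1.97-fold from 47.4 ± 6.45 to 24.04 ± 2.37 CPM, FOSL1 1.96-fold from 51.7 ± 7.30 to 26.4 ± 3.17 CPM and FOS 1.49-fold from 939 ± 114 to 630 ± 54.3 CPM. Cells of both groups had been dissociated from tissue before lysis.

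Genes of cholesterol synthesis were lower as a list at the preset correlation. Of 23 tested members, 11 fell, 0 rose and 12 did not pass, with 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.44e-05; adjusted p = 0.251 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 70.0 ± 6.48 to 42.1 ± 1.19 CPM (log2 fold change -0.73, SE 0.080, edgeR adjusted p = 1.55e-05). FDFT1, encoding squalene synthase, fell from 52.6 ± 4.42 to 32.5 ± 1.22 CPM, and the sterol sensor gene INSIG1 from 70.8 ± 3.61 to 44.8 ± 3.57 CPM. Fatty acid synthesis genes were not called as a list (2 of 12 rose, 1 fell and 9 did not pass, both over all genes and adjusted over the list alone; camera adjusted p = 0.850). SCD, the stearoyl-CoA desaturase, fell from 201 ± 7.22 to 143 ± 11.8 CPM. ELOVL6 and ACSL3 rose by 0.37 and 0.19 on the log2 scale. Without a single library the ELOVL6 adjusted p reached 0.0967, and that of ACSL3 lay between 0.0576 and 0.158 in all 6 such fits. The ACSL3 call also ended in 5 other settings, among them DESeq2 (adjusted p = 0.0621), the GC correction and no low-count filter.

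Apoptosis and survival regulators fell as a list (camera adjusted p = 0.00572; adjusted p = 0.465 with an estimated correlation), and the members that fell act in opposite ways. BIK, BID and BCL2L11, which promote death, went from 42.3 ± 2.27 to 23.9 ± 1.97 CPM, from 68.9 ± 8.54 to 42.8 ± 1.97 CPM and from 43.2 ± 1.29 to 30.4 ± 0.806 CPM. BCL2L1, which encodes the survival protein BCL-XL, fell from 79.5 ± 14.0 to 51.5 ± 6.07 CPM. Of 25 tested members, 12 fell, 1 rose (CASP8) and 12 did not pass, with 13 lower and 1 higher when adjusted over the list alone. The log2 fold change of BCL2L1 went from -0.63 to -0.39 with ALB as a covariate (edgeR adjusted p = 0.0409).

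Glycolysis genes fell as a list (camera adjusted p = 0.0134; adjusted p = 0.551 with an estimated correlation). Pyruvate kinase PKM went from 1253 ± 135 to 835 ± 53.8 CPM (log2 fold change -0.59, SE 0.082, edgeR adjusted p = 1.48e-04). PFKP fell from 83.3 ± 2.66 to 58.3 ± 5.13 CPM, ENO1 from 1645 ± 29.4 to 1238 ± 128 CPM and PGAM1 from 10.1 ± 3.31 to 4.03 ± 0.782 CPM. ENO1 and PGAM1 have many processed pseudogenes, so their counts are uncertain. Of 18 tested members, 8 fell, 1 rose (the lactate transporter gene SLC16A3) and 9 did not pass, with 10 lower and 2 higher when adjusted over the list alone. The list call ended without sgITPR3 replicate 2 (camera adjusted p = 0.0517). Hypoxia response genes were not called as a list. Of 24 tested members, 7 fell, 3 rose and 14 did not pass, with 9 lower and 3 higher when adjusted over the list alone (camera adjusted p = 0.115). It was called lower without sgCtrl replicate 3 (camera adjusted p = 0.0290), without sgITPR3 replicate 3 (0.00362), with ALB as a covariate (0.00988) and without a low-count filter (0.0127). CA9, the carbonic anhydrase induced by low oxygen, fell 2.95-fold from 43.1 ± 6.73 to 14.6 ± 7.16 CPM and NDRG1 1.71-fold from 1044 ± 77.1 to 612 ± 128 CPM. ANKRD37 and RORA of the same list rose, from 62.7 ± 8.62 to 101 ± 6.09 CPM and from 66.4 ± 3.81 to 96.2 ± 7.67 CPM.

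**Figure D4:**
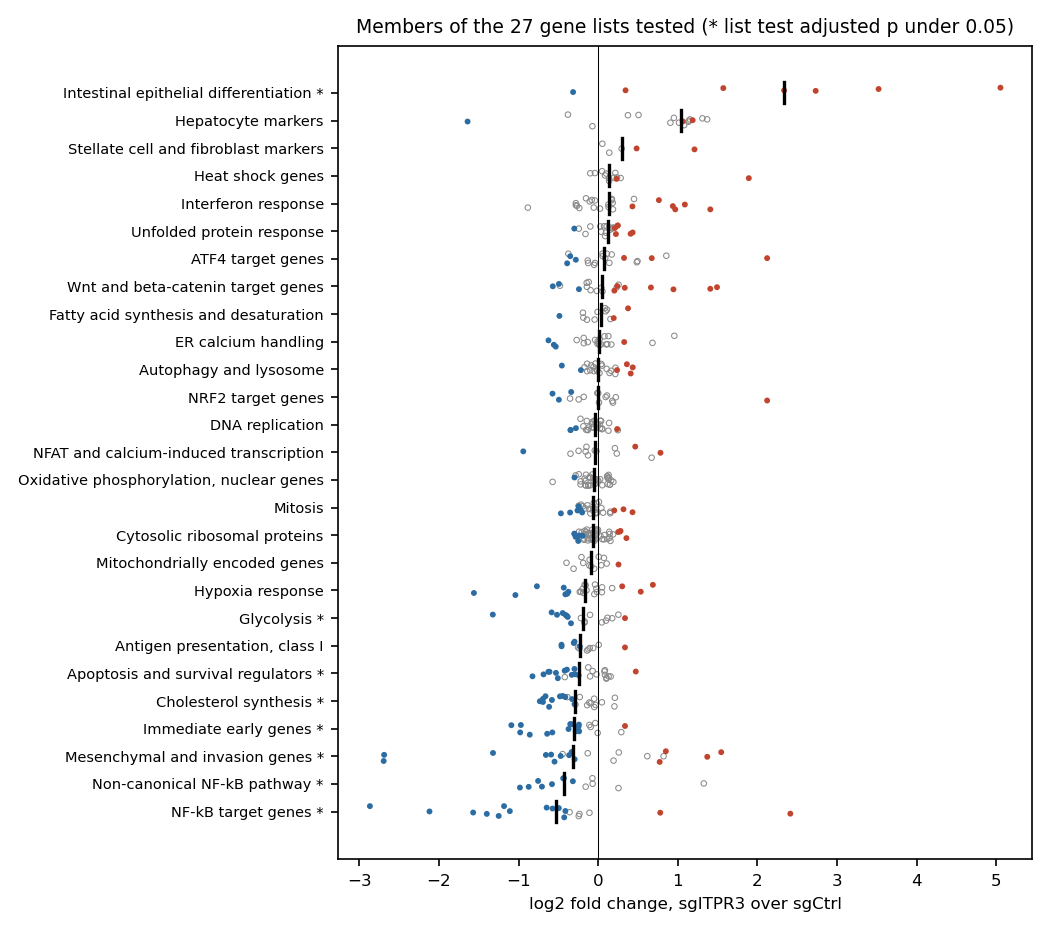
Log2 fold change (sgITPR3 over sgCtrl) of each tested member of the 27 gene lists tested, with members passing at an adjusted p under 0.05 filled (red higher, blue lower), others open, and the list median as a black line. The 8 lists with an asterisk had a camera adjusted p under 0.05, and points are spread vertically for legibility.

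Among endoplasmic reticulum calcium handling genes, 18 of 22 tested members did not pass, and the list was not called (camera adjusted p = 0.598). ITPR2 and the plasma membrane calcium channel genes ORAI1 and ORAI3 fell, the latter from 24.8 ± 1.48 to 17.2 ± 1.47 CPM for ORAI1 and from 23.4 ± 1.73 to 15.9 ± 1.13 CPM for ORAI3. STIM1, which encodes the store sensor that opens these channels, rose from 80.5 ± 6.25 to 101 ± 2.77 CPM. Its call ended with ALB as a covariate (log2 fold change 0.28 against 0.33, edgeR adjusted p = 0.0618). Over the list alone the numbers were also 3 lower and 1 higher. Of 13 tested NFAT and calcium-induced transcription genes, 2 rose, 1 fell and 10 did not pass, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.850). NFATC2 fell 1.92-fold from 41.1 ± 1.03 to 21.4 ± 3.75 CPM. NR4A1 rose from 60.1 ± 7.27 to 82.8 ± 11.9 CPM and EGR2 from 5.62 ± 0.672 to 9.63 ± 2.71 CPM. With ALB as a covariate the log2 fold change of NR4A1 was 0.36 against 0.47 (edgeR adjusted p = 0.0846) and that of EGR2 0.60 against 0.78 (edgeR adjusted p = 0.128). Without sgITPR3 replicate 2 that of EGR2 was 0.54 (edgeR adjusted p = 0.0706).

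Interferon response genes included 6 that rose, 0 that fell and 18 that did not pass among 24 tested, with the same numbers when adjusted over the list alone, and the list was not called (camera adjusted p = 0.187), though fry called it higher (adjusted p = 0.00622). The antiviral genes MX1 and OAS1 rose 2.13-fold and 1.96-fold, from 5.81 ± 0.903 to 12.4 ± 1.45 CPM and from 2.73 ± 0.223 to 5.34 ± 0.316 CPM, and IFI6 rose from 42.2 ± 2.34 to 56.9 ± 2.53 CPM. Class I antigen presentation genes were not called either (camera adjusted p = 0.0673). They were called lower without sgCtrl replicate 3 (camera adjusted p = 0.0291), without sgITPR3 replicate 1 (0.0209), with ALB as a covariate (0.0259), without a low-count filter (0.00631) and by fry (0.0259). Of 13 tested members, 5 fell, 1 rose (ERAP1) and 7 did not pass, also when adjusted over the list alone. TAPBP and TAP1, which encode parts of the peptide loading machinery, fell from 185 ± 16.9 to 134 ± 1.54 CPM and from 46.1 ± 3.35 to 33.4 ± 2.85 CPM. Both lie on chromosome 6 near ITPR3, TAPBP from 33299694 to 33314387 and TAP1 from 32845209 to 32853978. The 82 well-measured genes of the window from 30 to 40 Mb, ITPR3 left out, had a median log2 fold change of -0.17, against -0.05 on the other chromosomes, a window looked at after these values were seen. The windows from 20 to 30 Mb and from 10 to 20 Mb lay at -0.22 and -0.18, and chromosome 6 as a whole at -0.13.

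The lists for the unfolded protein response, ATF4, NRF2, autophagy and heat shock were not called. Of 20 unfolded protein response genes, 6 rose, 1 fell and 13 did not pass, with 8 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.153; fry adjusted p = 0.0349, higher). The chaperone gene DNAJC3 rose from 90.9 ± 4.79 to 123 ± 4.09 CPM and the transcription factor gene DDIT3 from 46.7 ± 5.20 to 61.9 ± 2.14 CPM. Of 20 ATF4 targets, 3 rose, 3 fell and 14 did not pass, with 3 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.598). SLC7A11, the cystine transporter gene that is also in the NRF2 list, rose 4.35-fold from 0.804 ± 0.338 to 3.51 ± 0.0636 CPM. Of 15 NRF2 targets, 1 rose, 3 fell and 11 did not pass, with 2 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.642). GCLM, a subunit of glutathione synthesis, fell from 67.0 ± 7.49 to 44.9 ± 3.53 CPM. Of 24 autophagy and lysosome genes, 4 rose, 2 fell and 18 did not pass, also over the list alone (camera adjusted p = 0.656), and the lysosomal protease gene CTSA fell from 80.4 ± 2.82 to 58.5 ± 4.63 CPM. Of 13 heat shock genes, CRYAB and HSPB1 rose and 11 did not pass, with 1 higher when adjusted over the list alone (camera adjusted p = 0.187). The heat shock list was called higher without sgCtrl replicate 1 (camera adjusted p = 0.0220), without sgITPR3 replicate 1 (0.0101) and with ALB as a covariate (2.83e-04). Leaving out single libraries raised the adjusted p of CRYAB to 0.0764 and that of HSPB1 to 0.166. HSPB1 had a log2 fold change of 0.38 with ALB as a covariate, against 0.23. All 4 tested metallothionein genes, too few for a list test, fell, MT2A from 2742 ± 230 to 1546 ± 146 CPM and MT1E from 832 ± 74.0 to 539 ± 34.1 CPM. Without a low-count filter, 7 metallothionein genes could be tested as a list and were called lower (camera adjusted p = 6.41e-05). Metallothioneins are near-identical in sequence and their counts are uncertain. For MT1F the adjusted p reached 0.0930 when single libraries were left out, with a log2 fold change of -0.26 against -0.39.

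Proliferation, ribosome and respiration lists were not called. Of 29 mitosis genes, 3 rose, 6 fell and 20 did not pass, with 3 higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.381). UBE2C and CDC20 fell, from 142 ± 11.1 to 103 ± 4.70 CPM and from 97.5 ± 8.74 to 76.2 ± 6.37 CPM. TOP2A and BIRC5, both on chromosome 17, rose from 940 ± 66.1 to 1267 ± 27.4 CPM and from 116 ± 1.6 to 145 ± 2.16 CPM. Genes of chromosome 17 as a set had a median log2 fold change of 0.16, the highest of any chromosome, a comparison made after the values were seen. Of 30 DNA replication genes, TYMS, LIG1 and MCM5 fell, CDC6 rose and 26 did not pass, also over the list alone (camera adjusted p = 0.564). Without single libraries the adjusted p of these 4 genes reached 0.0569, 0.104, 0.105 and 0.120. LIG1 had a log2 fold change of -0.12 with ALB as a covariate, against -0.35 (edgeR adjusted p = 0.544), and its call also ended with the GC correction (edgeR adjusted p = 0.0520). The calls of TYMS and MCM5 ended with the covariate as well (edgeR adjusted p = 0.121 and 0.205). Their log2 fold changes were then -0.28 against -0.35 for TYMS and -0.22 against -0.28 for MCM5. Of 52 cytosolic ribosomal protein genes, 4 rose, 7 fell and 41 did not pass, with 4 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.315). RPL24 rose from 255 ± 11.6 to 326 ± 16.1 CPM, and RPL38, on chromosome 17, from 981 ± 33.5 to 1192 ± 14.9 CPM. Of 37 nuclear genes of oxidative phosphorylation, SDHB fell and 36 did not pass, and 0 passed when adjusted over the list alone (camera adjusted p = 0.598). Of 13 mitochondrially encoded genes, MT-ND5 rose and 12 did not pass, again with 0 over the list alone (camera adjusted p = 0.598). MT-ND2, MT-ND6 and MT-CO3 (log2 fold changes -0.31, -0.40 and -0.19) were called lower with the replicate block and without a low-count filter. Without sgCtrl replicate 1, MT-ND2 and MT-ND6 were at -0.18 and -0.16 and did not pass. Without single libraries the adjusted p of SDHB reached 0.0767 and that of MT-ND5 0.151. These adjusted p values were 0.167 and 0.0570 in edgeR with ALB as a covariate. The log2 fold changes were then -0.24 against -0.30 for SDHB and 0.28 against 0.25 for MT-ND5.

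Markers of liver cell types were compared last. How mouse reads were handled is not given in the sources used here. Of 16 tested hepatocyte markers, APOA1 and CYP2E1 rose, SERPINA1 fell and 13 did not pass, also over the list alone, and the list was not called (camera adjusted p = 0.215). Without sgCtrl replicate 2, the sgCtrl library with the highest ALB level, it was called higher (camera adjusted p = 4.53e-08). APOA1 went from 4.50 ± 3.27 to 9.44 ± 2.58 CPM and CYP2E1 from 0.823 ± 0.161 to 1.88 ± 0.403 CPM. Their adjusted p values reached 0.150 and 0.0818 in edgeR when single libraries were left out. With ALB as a covariate the log2 fold change of APOA1 was 0.20 against 1.06 (edgeR adjusted p = 0.601) and that of CYP2E1 1.44 against 1.19 (edgeR adjusted p = 0.0540), and DESeq2 did not call APOA1 (adjusted p = 0.247). The log2 fold change of APOA1 was 1.83 without sgCtrl replicate 2. SERPINA1, which colorectal cancer cells can also express, fell 3.12-fold from 43.3 ± 3.86 to 13.9 ± 2.17 CPM. Of 3 tested macrophage markers, CTSS and LAPTM5 fell, from 5.82 ± 0.00569 to 2.85 ± 0.474 CPM and from 8.15 ± 0.870 to 4.37 ± 1.42 CPM. The log2 fold change of LAPTM5 was -0.79 with ALB as a covariate, against -0.91 (edgeR adjusted p = 0.0523). CD14 was at 1.33 ± 0.338 and 1.05 ± 0.561 CPM. Of 2 tested neutrophil markers, S100A9 fell from 12.7 ± 2.90 to 5.58 ± 1.94 CPM, and CXCR2 was at 10.1 ± 1.14 and 7.40 ± 1.37 CPM. CXCR2 passed when adjusted over the list alone and without sgCtrl replicate 1 (edgeR adjusted p = 0.0437). The endothelial marker EGFL7, the 1 tested, was at 1.74 ± 0.449 and 2.38 ± 0.111 CPM. Of 5 stellate cell and fibroblast markers, DES and COL1A1 rose and 3 did not pass, also over the list alone (camera adjusted p = 0.215; fry adjusted p = 0.0349, higher). DES went from 1.68 ± 0.720 to 3.89 ± 0.437 CPM, and COL1A1, on chromosome 17, from 5.61 ± 0.173 to 7.82 ± 0.885 CPM. Fitted with ALB as a covariate, the log2 fold change of DES was 0.79 against 1.21 (edgeR adjusted p = 0.146) and that of COL1A1 0.44 against 0.48 (edgeR adjusted p = 0.214). The adjusted p of COL1A1 reached 0.132 without single libraries and was 0.0774 in DESeq2. Both tested erythroid markers, the paralogs HBA1 and HBA2, rose, HBA2 from 13, 21 and 10 counts to 89, 99 and 104 counts, and HBA1 from 6, 3 and 1 counts to 21, 44 and 19 counts. Without a low-count filter, 6 erythroid markers could be tested and were called higher (camera adjusted p = 0.0226).

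In all, 3717 of 15804 tested genes passed at an adjusted p under 0.05 in the quasi-likelihood test of edgeR, 1835 higher and 1882 lower in sgITPR3. Of these, 955 also changed at least 2-fold, 681 higher and 274 lower. The groups did not overlap for 6215 genes, 39.3% of those tested, where 10% is the share that chance gives for 3 libraries against 3. Of 27 lists tested with camera, 7 fell and 1 rose, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. The self-contained test fry, which does not compare a list with other genes, called 12 lists. For calcium handling, NFAT, fatty acid synthesis and NRF2 genes the median, the mean and the test differed in sign. The number of changed genes was 2331 without sgITPR3 replicate 2 and 1982 with ALB as a covariate, and 13 of 32 lists were called without a low-count filter, 2 of them lists that were not tested with it.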

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

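ITPR3 stayed lower under every alternative (log2 fold change from -1.29 to -1.15). Leaving out single libraries gave 2331 to 4261 changed genes (1135 to 2121 higher, 1196 to 2140 lower), against 3717 (1835 and 1882) with all. A 2-fold threshold left 955 (681 and 274), by its construction. With ALB as a covariate, chosen after the data were seen like the GC correction and the fit without chromosome 17, 1982 genes changed (1000 higher, 982 lower). DESeq2 called 3416 and limma-voom 3856. Of the lists, 8 were called with all libraries, 7 to 10 without single libraries, 13 without a low-count filter (of 32 tested lists instead of 27; metallothioneins and erythroid markers were tested only there) and 0 with an estimated correlation (camera). The cause of these changes, apart from the threshold, was not tested. With the replicate number as a replicate block, 3877 genes (1896 higher, 1981 lower) and 8 lists changed. Deviations from the group mean correlated at -0.05, 0.01 and 0.10 between libraries of the same number, and those of sgCtrl 2 correlated best with those of sgITPR3 1 (0.11). Of 121 passing genes among the named ones, 86 kept their call and direction under every alternative and 0 turned. Sizes could still move: with ALB as a covariate the log2 fold change of TNFRSF12A went from -0.76 to -0.45 and that of BCL2L1 from -0.63 to -0.39. Genes that turned had not passed: ITPR1 (-0.000625) and CD14 (0.11) with ALB as a covariate, and ACTA2, from -0.0316 without sgITPR3 replicate 3 to a highest value of 0.12 without sgITPR3 replicate 2, and the cause was not tested. Depth limits genes near the floor of 0.121 to 0.161 CPM.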

Other observations

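Tests of the neuroendocrine members, of the dosage of chromosome 17, of the source of hepatocyte transcripts, of carry-over into intestinal genes and of the chromosome 12 run were chosen only after the result was seen.

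Neuroendocrine and synaptic vesicle genes rose in sgITPR3, including members other than those that prompted the list. This list was made after the largest changes were seen. Of its 30 listed members that were not among the genes seen first, 19 passed the low-count filter and were tested. Of these 19, 13 rose and 3 fell (camera p = 1.02e-07; p = 0.0187 with an estimated correlation). A gene near the floor in sgCtrl can pass the filter through sgITPR3 alone, which favours rises. SCG2 (means 0.170 and 0.730 CPM) and BSN (0.153 and 1.03 CPM) are such low members. SYP, SYT1 and SNAP25, genes of synaptic vesicles and their fusion, rose by 2.498, 2.64 and 1.85 on the log2 scale, and the prohormone convertase gene PCSK1 by 1.68. RAB3B, CPLX2 and PTPRN2 fell, from means of 43.2 to 13.3, 114 to 66.0 and 194 to 157 CPM. Among the controls, sgCtrl 2 had the highest CHGA and SCG3 levels (8.45 CPM against 3.28 and 3.47, and 7.06 against 3.60 and 5.02), below those of every sgITPR3 library. It also lay nearest to the sgITPR3 libraries on the first principal component, which held 59.8% of the variance (-18.0 against -42.3 and -45.8, and 31.1 to 38.4 in sgITPR3), and apart on the PC2 axis, with 14.5% (-37.8).

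Squamous and basal epithelial genes fell, again in a list made after the largest changes were seen. Of 31 listed members not seen first, 19 were tested, and of these 14 fell and 2 rose (camera p = 4.45e-13; p = 0.00141 with an estimated correlation). KLK6, TRIM29 and KRT80 had log2 fold changes of -1.32, -1.10 and -1.08. KRT15 and DSC2 rose. The keratin gene KRT5 fell less, from 1115 to 804 CPM (log2 fold change -0.47), and KRT17 did not pass (edgeR adjusted p = 0.290). One hypothesis is that loss of ITPR3 moved these cells from a basal to a secretory state, and another is that the sgITPR3 population grew from cells that already differed. The p values of 1.02e-07 and 4.45e-13 are compatible with both, and a second guide or a rescue could separate them.

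Genes of chromosome 17 lay higher in sgITPR3 as a set, by a median of 0.229 on the log2 scale over the other chromosomes (95% bootstrap interval 0.217 to 0.248). The bootstrap resampled genes, so its interval does not cover variation between libraries or cell populations. GC content does not account for it, as the difference was 0.241 after correction. Liver RNA that follows ALB does not either, as sgCtrl 2, with a high ALB level, differed from the other sgCtrl libraries by 0.0200. All 9 windows of 10 Mb lay above the median of the other chromosomes, as a dosage difference between the populations could produce. Such shifts were widespread: the medians of chromosomes 4, 10, 19 and 22 were 0.14, -0.19, -0.18 and -0.18, those of 18 of 23 chromosomes lay beyond all random gene lists, and 10 chromosomes had every window on the same side. The cause is left open. TOP2A, BIRC5, CDC6, RPL38 and COL1A1 lie on chromosome 17. RELB, PLAUR, BCL3 and KLF2 lie on chromosome 19, NFKB2, PFKP, PGAM1, PLAU and KLF6 on chromosome 10, and BIK and BID on chromosome 22. The falls of these genes on 10, 19 and 22 exceeded the medians there, but cannot be fully separated from the shifts. Other immediate early genes, among them FOSB, JUNB and JUND, also lie on chromosome 19, so the fall of that list is not fully separated either. No fit left out chromosomes 10, 19 or 22. DNA copy number was not analysed here.

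The hepatocyte transcript ALB ranged over 10.7-fold between libraries. The ratios of APOB, FGB and APOA1 to ALB ranged over at most 2.04-fold and that of CPS1 over 1.63-fold, as liver cells left after isolation could produce. The ratio of SERPINA1 to ALB ranged over 25.5-fold, so it did not follow ALB. TTR (3.22-fold) and FGG (9.94-fold) were too low to judge, at 0.214 and 0.0534 CPM in sgCtrl 3. Scaled by ALB, the excess in sgCtrl 2 predicted at least 50% of the rise for 3.11% of the 1835 higher genes and for 0 of 6 intestinal genes. RNA that follows ALB as in sgCtrl 2 thus does not account for most rises, though FABP1 had 19.3% of its rise predicted. Liver or blood RNA that does not follow ALB would be missed by this prediction. It gave -15.9% for the hepatocyte marker CYP2E1 and 7.45% and -2.36% for the erythroid genes HBA2 and HBA1, but 71.3% for APOA1. Of the 1882 lower genes, 7.55% had at least 50% of their fall predicted. With ALB as a covariate, 1982 genes changed.

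On chromosome 12, 7 of 8 neighbouring genes from BMAL2-AS1 to HMGB1P49 rose, 6 of them 2-fold or more. Shuffles of all genes reached that count at most (median of their highest counts 4). The run was not alone: 6 windows held that count in the data, the others on chromosomes 13 and 17. RARS1P1 lies inside SMCO2, and BMAL2-AS1 overlaps BMAL2, so these may share reads. With overlapping genes left out, 758 of 1000 shuffles of gene order held a window with as many genes 2-fold higher as the 4 left here, so a coincidence of neighbours stays open. In the data 40 windows over all chromosomes then held as many, and the highest count was 6. The excess in sgCtrl 2, scaled by ALB, predicted a median of -0.379% of the rise. SMCO2 and PPFIBP1 differed by 1.604 on the log2 scale (SE 0.119), which a gain of copies of the whole segment alone does not give, and an insertion or a new promoter might be sought in DNA.

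Of the 10 ways to split the 6 libraries into 3 and 3, only 1 called as many as the 3717 genes of the real split, and the highest other number in edgeR was 0. So few splits cannot give a share under 0.05.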
